A study of Arabidopsis thaliana with 24 samples.

How the data were processed

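The data are RNA sequencing read counts from Arabidopsis leaves, given as tables of counts per gene and per transposable element (TE). There are 12 RNA libraries in 6 groups of 2: 1n (haploid), 2n (diploid), the doubled-haploid lines DH6, DH9 and DH14, and sDH, a name the labels do not spell out. Plants were 2 weeks old, grown on soil at 22 °C under long days (16 h light, 8 h dark), and seeds were stratified for 2 days at 4 °C. Leaves 6, 7 and 8 were taken. The labels name poly(A) selection, NEBNext Ultra libraries and 150 bp paired-end reads on a NovaSeq. They call the 2 libraries of a group biological replicates and do not say whether these are separate plants, sowings or harvests, nor at what hour leaves were taken. All p-values here measure only the spread between these libraries. The 12 DNA methylation samples of the same series were not analysed here.

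According to the submitters' processing notes, reads were aligned to TAIR10 with HISAT2 and counted with Subread, and DESeq2 was used for differential expression. Versions, annotation, strand setting and the handling of reads with several hits are not given in the sources used here. Counts of genes with near-identical copies, such as the LHCB2 family, and of TE copies therefore rest on an unknown rule for shared reads. The same holds for TEs and genes that overlap on opposite strands.

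Each of 10 tables gives 27416 genes or 31189 TEs. The 1n columns stand in every table with the same counts, so that the tables were joined on them. Columns named WT were taken as 2n because no other group was left for them. Columns of DH6 and sDH carry the numerals II and III where the labels have replicates 1 and 2, so these libraries keep the names II and III here. The gene table of sDH holds the first 1n column in both 1n places, and both 1n libraries were taken from the other tables. Of the gene identifiers, 26719 matched the reference table (TAIR10.1) and 10376 had a symbol. No coordinates were used.

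Analysis was done in R 4.3.3 with edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0. Features with too few counts were removed by edgeR's filterByExpr (minimum count 10, minimum total 15), leaving 19201 genes and 1372 TEs. Genes were normalised by the trimmed mean of M values (TMM), and TEs took the gene library sizes. One quasi-likelihood model was fitted to all 12 libraries with a mean per group. Tested were 2n against 1n, each of DH6, DH9, DH14 and sDH against 1n and against 2n, and differences among DH6, DH9 and DH14 by an F-test, followed by the 3 pairs of lines. A feature rose, fell or changed when its Benjamini-Hochberg adjusted p from edgeR's quasi-likelihood test lay under 0.05. Levels are in CPM, and log2 changes come with their standard error (SE).

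When a group had no counts for a feature, the fold is given as at least the level in the other group over a floor of 3 counts in the group. With 1 to 3 counts, the count ratio has a 95% interval of read sampling alone. One count equals 0.0449 to 0.0632 CPM in these libraries, and the floor of 3 counts equals 0.135 to 0.189 CPM in a single library.

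Fixed lists of known Arabidopsis genes, 26 in number and 1 of them of mobile TE copies, were written from general knowledge before the data were examined. They are cell division and DNA replication, photosynthesis, rapid touch and stress response, salicylic acid defence, NLR immune receptors, glucosinolate synthesis, jasmonate response, heat shock, cold and abscisic acid, circadian clock, flowering time, and senescence and carbon starvation. Further lists are anthocyanin and flavonoid synthesis, iron homeostasis, phosphate starvation, DNA damage, endocycle, centromere and kinetochore, DNA methylation machinery with RNA-directed DNA methylation, and loci silenced by DNA methylation. Markers of root, flower and pollen, seed, shoot meristem, and guard cell and trichome were listed to see other tissue. With members among the tested genes, 23 gene lists were tested by limma's camera with its preset correlation of 0.01 between genes and again with an estimated correlation, adjusted over the lists of a comparison. Members were also counted after adjusting over the list alone.

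Also fixed beforehand were the comparisons, tests, alternatives and the rule that picks the genes to name. That rule takes the 6 highest and 6 lowest log2 changes per comparison among changed nuclear genes with a symbol, a mean of 20 counts in the higher group and no overlap between the libraries of the 2 groups. It adds up to 4 members with the smallest adjusted p from each passing list, 3 highest and 3 lowest TEs, and 6 genes with the largest change shared by the 3 lines. CENH3, MET1, CMT2, CMT3, DRM2, DDM1 and ROS1 were read in each comparison whatever their values. The text gives part of the genes so picked, mostly those whose calls survive each left-out library, and prints the values where a call it gives does not. Among alternatives, 3 were added after the data were seen: fitting the repeated 1n column, fitting the 8 numbered libraries alone, and comparing DH9 with DH14 without DH6.

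The procedure was tried on simulated counts with 2 libraries per group. In 2n against 1n the procedure found 64.6% of genes shifted by log2 1 and 96% by log2 2, with 4.22% of calls false. In DH9 against 2n these were 58, 90 and 3.27%, and among lines 60, 93 and 4.97%. For TEs they were 41.1, 75.3 and 4.27% in 2n against 1n, 51, 80.6 and 6.57% in DH9 against 2n, and 53.1, 82.7 and 5.04% among lines. Camera called the 1 shifted and 0 of 20 unshifted lists of independent genes under both correlations, leaving correlated lists untested. Unchanged groups were also simulated 20 times.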

Results

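Libraries held 16484799 to 22146896 counts in genes. Counts in TEs amounted to 9.08 and 9.19 per mille of the gene counts in the 1n libraries and to 11.1 to 12.4 per mille in the others. Genes of the organelles took 0.031 to 0.0616% of the counts and the 10 largest genes 9.49 to 13%. Levels below are mean ± SD over the 2 libraries of a group (n = 2), the control given before the other group. Correlation between the libraries of a group was 0.97 in 1n, 0.984 in DH6 and 0.987 or 0.988 in the other groups. Each pair differed by more than sampling of reads, with a chi-square per degree of freedom of 25.2 in 1n, 10.2 in 2n, 13.4 in DH6, 4.06 in DH9, 6.08 in DH14 and 7.32 in sDH. Between groups, the mean correlation of single libraries was highest for DH9 and DH14 (r = 0.979), followed by DH6 and sDH (0.969), and lowest for 1n and sDH (0.908). The first principal components took 36.9, 22 and 10.5% of the variance. Median log2 differences of whole chromosomes between a library and the 2n mean stayed between -0.0619 and 0.0622.

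Libraries of DH6 held counts at many features silent elsewhere. Of 3947 genes without a count in any library of the other groups, 459 had a count in DH6 II and 821 in DH6 III (11.6 and 20.8%). Of 26043 such TEs, 1443 and 2046 had a count (5.54 and 7.86%). Thinned to equal totals, DH6 was also set beside each other group, in features silent in the remaining 4 groups. DH6 libraries then had a count in at least 9.59% of genes and 4.64% of TEs, and those of the other groups in at most 5.49 and 1.36%. Most of these features were too low to be tested. Of 3 tested root markers 2 passed edgeR as higher in DH6 against both controls, while their list did not pass (camera adjusted p = 0.315 and 0.246).

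**Figure D1:**
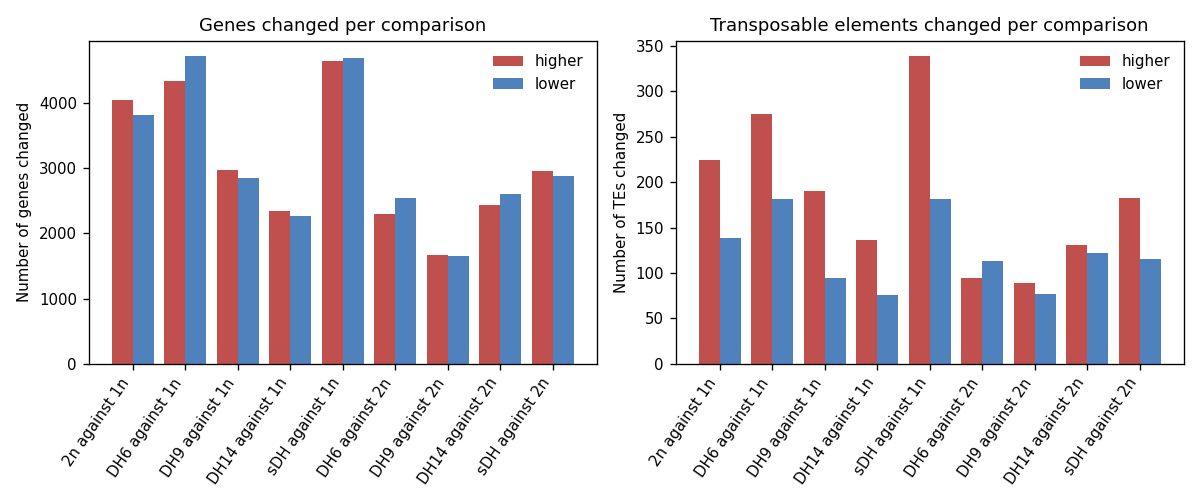
Numbers of genes and of TEs that rose or fell in each comparison. Each panel gives genes or TEs, with separate bars for higher and lower.

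Leaves of 2n differed from 1n in genes of cell division, stress signals, the clock and photosynthesis. In no comparison was harvest hour tested as a cause for touch, photosynthesis or glucosinolate genes. Mitotic and replication genes were higher in 2n, as were fast-responding transcription factors of touch and wounding. Most photosynthesis genes and MYB28, a regulator of aliphatic glucosinolates, defence compounds of the cabbage family, were lower. The morning clock genes CCA1 and LHY stood near zero in 2n and the evening gene ELF4 high. In 2n against 1n 4040 genes rose and 3812 fell. Cell division genes moved together: 29 of 31 rose, 2 did not pass (median log2 change 1.55, 29 up adjusted over the list alone, camera adjusted p = 1.43e-14, or 0.429 with an estimated correlation). The mitotic cyclin gene CYC1BAT (CYCB1;2) rose (5.83 ± 0.835 to 29.9 ± 2.1 CPM, log2 change 2.36, SE 0.149, edgeR adjusted p = 1.18e-06), and so did SYP111 (KNOLLE), the syntaxin of the cell plate (9.63 ± 0.676 to 43.5 ± 1.78 CPM, log2 change 2.18, SE 0.15, edgeR adjusted p = 1.98e-06). In the rapid touch and stress list 20 of 22 rose, 2 did not pass (median log2 change 2.28, 21 up adjusted over the list alone, camera adjusted p = 3.75e-08, or 0.607 with an estimated correlation). ERF104 rose (16.9 ± 5.7 to 267 ± 16.3 CPM, log2 change 3.99, SE 0.318, edgeR adjusted p = 5.18e-06). Among photosynthesis genes 30 of 33 fell, 3 did not pass (median log2 change -0.78, 31 down adjusted over the list alone, camera adjusted p = 7.09e-14, or 0.429 with an estimated correlation). LHCB2.3 fell (2292 ± 212 to 289.6 ± 39.7 CPM, log2 change -2.98, SE 0.11, edgeR adjusted p = 4.27e-08). In glucosinolate synthesis 1 of 25 rose and 19 fell, 5 did not pass (median log2 change -1.50, 1 up and 19 down adjusted over the list alone, camera adjusted p = 0.000107, or 0.857 with an estimated correlation). MYB28 fell (91.2 ± 15.6 to 27.1 ± 4.12 CPM, log2 change -1.75, SE 0.13, edgeR adjusted p = 3.19e-06).

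Of centromere and kinetochore genes 4 of 8 rose, 4 did not pass (median log2 change 0.50, 4 up adjusted over the list alone, camera adjusted p = 0.0396, or 0.429 with an estimated correlation). CENP-C rose (17 ± 2.16 to 27.9 ± 0.831 CPM, log2 change 0.71, SE 0.135, edgeR adjusted p = 0.0017). NDC80 (AT3G54630) rose (2.75 ± 0.138 to 5.59 ± 0.182 CPM, log2 change 1.02, SE 0.175, edgeR adjusted p = 0.000903). CCA1 fell (125 ± 75.6 to 1.03 ± 0.0127 CPM, log2 change -6.92, SE 0.476, edgeR adjusted p = 1.94e-06) and LHY fell (108 ± 97 to 0.411 ± 0.024 CPM, log2 change -8.01, SE 0.813, edgeR adjusted p = 2.67e-05). ELF4 rose (3.07 ± 2.54 to 71 ± 6.2 CPM, log2 change 4.54, SE 0.377, edgeR adjusted p = 6.85e-06). The clock list as a whole did not pass, with 9 of 19 genes up and 9 down (camera adjusted p = 0.831). The heat-shock factor gene HSFA2 rose (log2 change 4.39, SE 0.756, edgeR adjusted p = 0.000942) and the drought and heat regulator DREB2A rose (2.82 ± 0.651 to 73.9 ± 50.7 CPM, log2 change 4.71, SE 0.444, edgeR adjusted p = 1.6e-05). UMAMIT28, a gene of an amino acid transporter family, fell at least 45-fold (112 against 0 counts, edgeR adjusted p = 0.000218). Of the salicylic acid list 7 genes rose and 4 fell, and of NLR receptors 7 rose and 2 fell, each with camera adjusted p = 0.489. Of 42 genes of DNA methylation 13 rose and 3 fell (camera adjusted p = 0.0977).

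DH6 leaves against 1n combined higher levels of cell division genes with lower levels of immune and senescence genes. Salicylic acid, the hormone of resistance to biotrophic pathogens, is made by ICS1 (EDS16) and acts with PAD4, and both genes fell. Most intracellular immune receptors and most genes of leaf ageing fell with them. In this comparison 4335 genes rose and 4713 fell. In cell division 29 of 31 rose, 2 did not pass (median log2 change 1.79, 29 up adjusted over the list alone, camera adjusted p = 2.25e-15, or 0.192 with an estimated correlation). CYC1BAT rose (5.83 ± 0.835 to 31.6 ± 5.25 CPM, log2 change 2.44, SE 0.148, edgeR adjusted p = 2.57e-06), and the growth-regulating factor GRF9 rose (0.215 ± 0.125 to 2.88 ± 0.25 CPM, log2 change 3.70, SE 0.45, edgeR adjusted p = 8.34e-05). In salicylic acid defence 24 of 27 fell, 3 did not pass (median log2 change -2.15, 24 down adjusted over the list alone, camera adjusted p = 9.38e-10, or 0.158 with an estimated correlation). NUDT6 fell (62.8 ± 14.1 to 6.5 ± 0.605 CPM, log2 change -3.27, SE 0.185, edgeR adjusted p = 1.92e-06) and ICS1 (EDS16) fell (45.9 ± 3.77 to 14.2 ± 0.08 CPM, log2 change -1.69, SE 0.132, edgeR adjusted p = 7.16e-06). PAD4 fell (52.6 ± 0.976 to 11.7 ± 2.53 CPM, log2 change -2.17, SE 0.177, edgeR adjusted p = 8.25e-06). Of NLR receptors 18 of 25 fell, 7 did not pass (median log2 change -0.61, 19 down adjusted over the list alone, camera adjusted p = 2.62e-05, or 0.471 with an estimated correlation). ADR1, a helper receptor, fell (16.4 ± 3.54 to 4.13 ± 0.0588 CPM, log2 change -1.99, SE 0.187, edgeR adjusted p = 1.83e-05). In the senescence list 1 of 15 rose and 10 fell, 4 did not pass (median log2 change -1.95, 1 up and 11 down adjusted over the list alone, camera adjusted p = 0.00371, or 0.466 with an estimated correlation). The senescence regulator NAP fell (5.92 ± 1.09 to 0.162 ± 0.0388 CPM, log2 change -5.14, SE 0.563, edgeR adjusted p = 4.31e-05). Of touch genes 16 of 22 fell, 6 did not pass (median log2 change -1.44, 16 down adjusted over the list alone, camera adjusted p = 0.000991, adjusted p = 0.571 with an estimated correlation), among them TCH3 (304 ± 69.4 to 50.7 ± 6.1 CPM, log2 change -2.58, SE 0.243, edgeR adjusted p = 1.82e-05).

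In heat shock 1 of 16 rose and 8 fell, 7 did not pass (median log2 change -1.42, 1 up and 8 down adjusted over the list alone, camera adjusted p = 0.0342, adjusted p = 0.471 with an estimated correlation), and HSP90.1 fell (10.3 ± 6.13 to 1.97 ± 0.512 CPM, log2 change -2.37, SE 0.39, edgeR adjusted p = 0.000562). Photosynthesis went down in DH6 against 1n: 19 of 33 fell, 14 did not pass (median log2 change -0.26, 20 down adjusted over the list alone, camera adjusted p = 8.96e-05, adjusted p = 0.57 with an estimated correlation). LHCB2.3 fell (2292 ± 212 to 981 ± 56.4 CPM, log2 change -1.23, SE 0.103, edgeR adjusted p = 9.93e-06). Of the DNA damage list 8 of 16 rose, 8 did not pass (median log2 change 0.54, 8 up adjusted over the list alone, camera adjusted p = 0.00541, adjusted p = 0.192 with an estimated correlation). The damage-responsive cyclin CYCB1;1, which also marks division, rose (1.21 ± 0.00833 to 7.94 ± 0.236 CPM, log2 change 2.71, SE 0.238, edgeR adjusted p = 1.19e-05). Of centromere genes 4 of 8 rose, 4 did not pass (median log2 change 0.62, 4 up adjusted over the list alone, camera adjusted p = 0.0131, adjusted p = 0.339 with an estimated correlation). In DNA methylation 14 of 42 rose and 3 fell, 25 did not pass (median log2 change 0.21, 13 up and 3 down adjusted over the list alone, camera adjusted p = 0.0149, adjusted p = 0.57 with an estimated correlation). VIM1, a partner of MET1, rose (21.8 ± 2.03 to 46.2 ± 4.92 CPM, log2 change 1.08, SE 0.116, edgeR adjusted p = 3.95e-05). BGLU11, a beta-glucosidase gene, fell at least 38-fold (85 against 0 counts, edgeR adjusted p = 9.07e-05).

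DH9 leaves against 1n showed higher levels of division genes and a near loss of PR1, the standard marker of salicylic acid defence. FMO1, which makes the mobile resistance signal N-hydroxypipecolic acid, was without a count. The floral repressor FLC and the evening gene FKF1 rose. Here 2970 genes rose and 2849 fell (5819 in all). Without a DH9 library fewer passed, 3830 without DH9 1 and 3059 without DH9 2. In cell division 29 of 31 rose, 2 did not pass (median log2 change 1.45, 29 up adjusted over the list alone, camera adjusted p = 1.43e-16, or 0.33 with an estimated correlation). CYC1BAT rose (5.83 ± 0.835 to 22.9 ± 1.37 CPM, log2 change 1.97, SE 0.15, edgeR adjusted p = 1.51e-05). Of salicylic acid genes 2 of 27 rose and 13 fell, 12 did not pass (median log2 change -1.37, 3 up and 14 down adjusted over the list alone, camera adjusted p = 4.61e-05, or 0.355 with an estimated correlation). PR1 fell (316 ± 212 to 0.367 ± 0.101 CPM, log2 change -9.73, SE 1.11, edgeR adjusted p = 0.000199). FMO1 fell at least 34.9-fold (88 against 0 counts, edgeR adjusted p = 0.00212). Of photosynthesis genes 17 of 33 fell, 16 did not pass (median log2 change -0.32, 23 down adjusted over the list alone, camera adjusted p = 4.88e-06, adjusted p = 0.596 with an estimated correlation), RCA (rubisco activase) among them (10870 ± 524 to 6897 ± 407 CPM, log2 change -0.66, SE 0.0676, edgeR adjusted p = 7.14e-05). In DNA methylation 14 of 42 rose and 1 fell, 27 did not pass (median log2 change 0.26, 14 up and 1 down adjusted over the list alone, camera adjusted p = 0.00226, or 0.577 with an estimated correlation). CLSY1 (CHR38), which recruits RNA polymerase IV to its targets, rose (5.82 ± 0.346 to 13.6 ± 0.899 CPM, log2 change 1.22, SE 0.162, edgeR adjusted p = 0.000324). FKF1 rose (5.13 ± 1.59 to 54 ± 3.98 CPM, log2 change 3.40, SE 0.231, edgeR adjusted p = 8.49e-06). FLC rose with a count ratio of 55.5 (95% interval 9.61 to 2220, edgeR adjusted p = 0.00142).

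DH14 leaves stood closest to 1n among the diploid groups (r = 0.952), with higher levels of division genes and lower levels of salicylic acid genes. Most touch genes that passed rose, ERF5 among them, while WRKY46 fell. The demethylase ROS1 rose and its relative DML3 fell. In DH14 against 1n 2333 genes rose and 2270 fell (4603 in all). Leaving out DH14 1 gave 2205 and leaving out DH14 2 gave 2295. In cell division 28 of 31 rose, 3 did not pass (median log2 change 1.37, 30 up adjusted over the list alone, camera adjusted p = 3.71e-20, adjusted p = 0.215 with an estimated correlation). The replication helicase MCM6 rose (11.1 ± 0.457 to 22.9 ± 0.594 CPM, log2 change 1.04, SE 0.0906, edgeR adjusted p = 6.47e-05). In salicylic acid defence 11 of 27 fell, 16 did not pass (median log2 change -0.80, 1 up and 11 down adjusted over the list alone, camera adjusted p = 0.000314, adjusted p = 0.408 with an estimated correlation). PR1 fell (316 ± 212 to 1.31 ± 0.223 CPM, log2 change -7.90, SE 0.959, edgeR adjusted p = 0.000524). Of touch genes 8 of 22 rose and 2 fell, 12 did not pass (median log2 change 1.00, 14 up and 2 down adjusted over the list alone, camera adjusted p = 0.00198, adjusted p = 0.695 with an estimated correlation). ERF5 rose (4.84 ± 1.28 to 19.4 ± 4.01 CPM, log2 change 2.00, SE 0.23, edgeR adjusted p = 0.000263). WRKY46 fell (20.6 ± 1.26 to 9.31 ± 0.686 CPM, log2 change -1.14, SE 0.226, edgeR adjusted p = 0.00489). In DNA methylation 14 of 42 rose and 1 fell, 27 did not pass (median log2 change 0.29, 16 up and 1 down adjusted over the list alone, camera adjusted p = 0.000644, adjusted p = 0.408 with an estimated correlation). DML3 fell (12.5 ± 0.935 to 5.69 ± 1.21 CPM, log2 change -1.13, SE 0.195, edgeR adjusted p = 0.00251) and NRPE1 (NRPD1B), the large subunit of RNA polymerase V, rose (log2 change 0.75, SE 0.138, edgeR adjusted p = 0.00345). FLC rose with a count ratio of 70.9 (95% interval 12.4 to 2830, edgeR adjusted p = 0.00149). Photosynthesis did not pass in DH14 (1 up, 4 down, camera adjusted p = 0.146).

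Leaves of sDH had lower levels of defence genes than 1n. PR1 had no count in either library. Of genes of darkness and sugar shortage, SEN1 and the branched-chain amino acid aminotransferase BCAT-2 rose, while their list did not pass. The aliphatic glucosinolate regulator MYB28 and the indolic MYB51 fell. In sDH against 1n 4631 genes rose and 4687 fell. Salicylic acid genes went down: 26 of 27 fell, 1 did not pass (median log2 change -2.83, 26 down adjusted over the list alone, camera adjusted p = 2.61e-11, adjusted p = 0.11 with an estimated correlation). PR1 fell at least 4010-fold (10105 against 0 counts, edgeR adjusted p = 5.74e-05) and ALD1 fell at least 119-fold (300 against 0 counts, edgeR adjusted p = 3.11e-05). PR5 fell (279 ± 86.1 to 8.75 ± 3.85 CPM, log2 change -4.98, SE 0.4, edgeR adjusted p = 5.74e-06). Of NLR receptors 19 of 25 fell, 6 did not pass (median log2 change -0.62, 22 down adjusted over the list alone, camera adjusted p = 3.69e-06, adjusted p = 0.514 with an estimated correlation). In cell division 29 of 31 rose, 2 did not pass (median log2 change 1.57, 29 up adjusted over the list alone, camera adjusted p = 2.47e-13, adjusted p = 0.258 with an estimated correlation). SYP111 rose (9.63 ± 0.676 to 48 ± 2.95 CPM, log2 change 2.32, SE 0.151, edgeR adjusted p = 2.07e-06). In glucosinolate synthesis 24 of 25 fell, 1 did not pass (median log2 change -1.66, 1 up and 24 down adjusted over the list alone, camera adjusted p = 7.18e-07, adjusted p = 0.517 with an estimated correlation). MYB51 fell (16.2 ± 3.75 to 2.11 ± 0.507 CPM, log2 change -2.91, SE 0.241, edgeR adjusted p = 6.73e-06). MYB28 fell (91.2 ± 15.6 to 37.1 ± 0.224 CPM, log2 change -1.30, SE 0.128, edgeR adjusted p = 1.85e-05).

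Of jasmonate genes in sDH 7 of 25 fell, 18 did not pass (median log2 change -1.70, 2 down adjusted over the list alone, camera adjusted p = 0.0302, adjusted p = 0.837 with an estimated correlation). TAT3 fell (88.8 ± 26.3 to 0.315 ± 0.28 CPM, log2 change -8.02, SE 1.28, edgeR adjusted p = 0.000435) and the defensin PDF1.2 fell (15.2 ± 8.58 to 0.199 ± 0.115 CPM, log2 change -6.15, SE 1.34, edgeR adjusted p = 0.00318). Photosynthesis fell in part: 1 of 33 rose and 16 fell, 16 did not pass (median log2 change -0.22, 1 up and 16 down adjusted over the list alone, camera adjusted p = 0.0302, adjusted p = 0.824 with an estimated correlation). PSBO1 fell (6873 ± 117 to 4176 ± 359 CPM, log2 change -0.72, SE 0.0802, edgeR adjusted p = 4.01e-05). In the DNA damage list 8 of 16 rose and 1 fell, 7 did not pass (median log2 change 0.57, 8 up and 1 down adjusted over the list alone, camera adjusted p = 0.0302, adjusted p = 0.389 with an estimated correlation), with CYCB1;1 up (1.21 ± 0.00833 to 7.76 ± 0.708 CPM, log2 change 2.68, SE 0.24, edgeR adjusted p = 1.03e-05). Of DNA methylation genes 16 of 42 rose and 2 fell, 24 did not pass (median log2 change 0.37, 14 up and 2 down adjusted over the list alone, camera adjusted p = 0.00227, adjusted p = 0.517 with an estimated correlation). NRPE1 (NRPD1B) rose (10.3 ± 1.53 to 20.9 ± 0.0391 CPM, log2 change 1.02, SE 0.137, edgeR adjusted p = 0.000141). SEN1 rose (13.9 ± 6.31 to 636 ± 159 CPM, log2 change 5.51, SE 0.357, edgeR adjusted p = 2.07e-06). BCAT-2 rose (0.649 ± 0.0247 to 89.4 ± 22.8 CPM, log2 change 7.09, SE 0.277, edgeR adjusted p = 3.72e-07), yet the senescence list split (4 up, 4 down, camera adjusted p = 0.89).

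**Figure D2:**
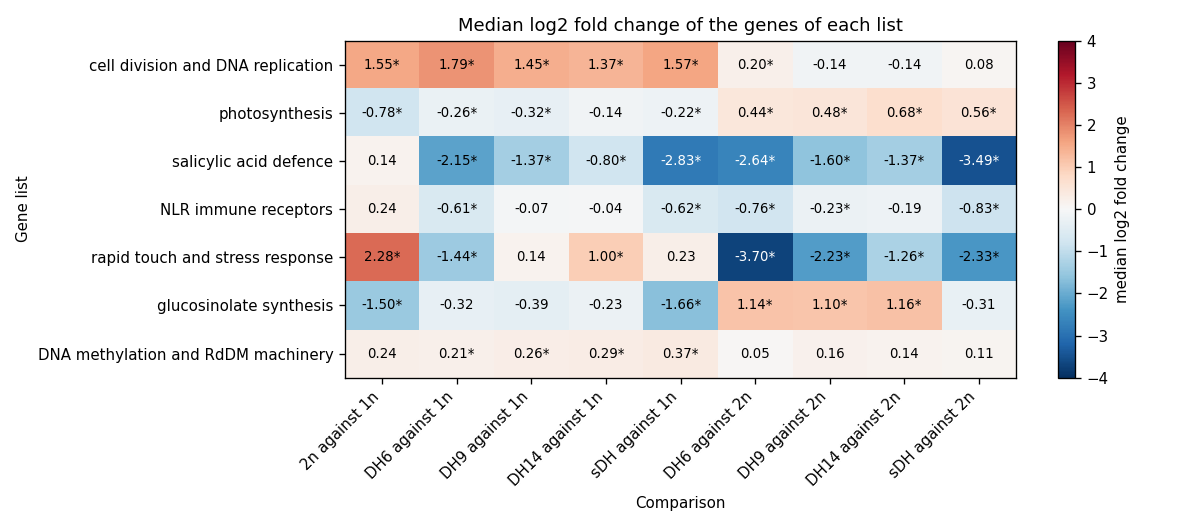
Median log2 change of 7 gene lists in each comparison. A star marks a camera adjusted p under 0.05 at the preset correlation.

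Most salicylic acid, touch and heat-shock genes fell in DH6 against 2n, and most photosynthesis genes rose. PAD3, the last enzyme of the phytoalexin camalexin, and SARD1, an activator of salicylic acid synthesis, fell. The aliphatic regulator MYB28 rose while the indolic MYB51 fell. Seed dormancy gene DOG1 and the kinase gene CIPK20 rose. In DH6 against 2n 2288 genes rose and 2533 fell (4821 in all), and with a minimum 2-fold change 561 and 1213. The number was 2632 without 2n 2, 2884 without DH6 II and 2838 without DH6 III. In salicylic acid defence 26 of 27 fell, 1 did not pass (median log2 change -2.64, 26 down adjusted over the list alone, camera adjusted p = 5.46e-19, adjusted p = 0.0291 with an estimated correlation). PAD3 fell (40.1 ± 10.5 to 0.83 ± 0.0338 CPM, log2 change -5.58, SE 0.462, edgeR adjusted p = 1.79e-05). SARD1 fell (93.3 ± 18.9 to 7.75 ± 3.39 CPM, log2 change -3.59, SE 0.3, edgeR adjusted p = 1.8e-05). Of touch genes 22 of 22 fell (median log2 change -3.70, 22 down adjusted over the list alone, camera adjusted p = 5.46e-19, adjusted p = 0.331 with an estimated correlation). WRKY46 fell (59.5 ± 11.1 to 2.51 ± 0.264 CPM, log2 change -4.56, SE 0.257, edgeR adjusted p = 2.94e-06). ERF104 fell (267 ± 16.3 to 14.2 ± 2.04 CPM, log2 change -4.24, SE 0.32, edgeR adjusted p = 1.1e-05). Of NLR receptors 18 of 25 fell, 7 did not pass (median log2 change -0.76, 18 down adjusted over the list alone, camera adjusted p = 4.54e-10, adjusted p = 0.331 with an estimated correlation). RPS2 fell (38.1 ± 2.88 to 13 ± 0.362 CPM, log2 change -1.56, SE 0.13, edgeR adjusted p = 1.81e-05). In photosynthesis 20 of 33 rose and 1 fell, 12 did not pass (median log2 change 0.44, 23 up and 1 down adjusted over the list alone, camera adjusted p = 2.04e-09, adjusted p = 0.374 with an estimated correlation). LHCB2.1 rose (817 ± 140 to 2706 ± 133 CPM, log2 change 1.73, SE 0.101, edgeR adjusted p = 3.6e-06). In glucosinolate synthesis 16 of 25 rose and 2 fell, 7 did not pass (median log2 change 1.14, 20 up and 2 down adjusted over the list alone, camera adjusted p = 0.000188, adjusted p = 0.499 with an estimated correlation). MYB28 rose (27.1 ± 4.12 to 52 ± 1.88 CPM, log2 change 0.94, SE 0.128, edgeR adjusted p = 0.000397). MYB51 fell (21.6 ± 4.74 to 2.38 ± 0.384 CPM, log2 change -3.18, SE 0.231, edgeR adjusted p = 8.8e-06).

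In heat shock 1 of 16 rose and 9 fell, 6 did not pass (median log2 change -1.92, 1 up and 9 down adjusted over the list alone, camera adjusted p = 0.00839, adjusted p = 0.331 with an estimated correlation), with HSFA2 down (35.5 ± 35.1 to 0.394 ± 0.113 CPM, log2 change -6.48, SE 0.891, edgeR adjusted p = 0.000409). Of senescence genes 8 of 15 fell, 7 did not pass (median log2 change -1.42, 8 down adjusted over the list alone, camera adjusted p = 0.000371, adjusted p = 0.331 with an estimated correlation), and NYC1, which opens chlorophyll breakdown, fell (332 ± 17.1 to 124 ± 18.8 CPM, log2 change -1.42, SE 0.126, edgeR adjusted p = 2.59e-05). In anthocyanin synthesis 4 of 16 rose, 12 did not pass (median log2 change 1.04, 4 up adjusted over the list alone, camera adjusted p = 0.0117, adjusted p = 0.419 with an estimated correlation). Of these TT4 rose (edgeR adjusted p = 0.00989) and EGL3 rose (edgeR adjusted p = 0.0141). These calls ended without 1 library: edgeR adjusted p = 0.0927 for TT4 without 2n 2 and 0.0718 without DH6 II, and 0.116 for EGL3 without 2n 2 and 0.0789 without DH6 III. Of guard cell and trichome markers 3 of 7 rose, 4 did not pass (median log2 change 0.46, 4 up adjusted over the list alone, camera adjusted p = 0.0385, adjusted p = 0.331 with an estimated correlation). GC1 (AT1G22690) rose (log2 change 1.03, SE 0.153, edgeR adjusted p = 0.000669) and MYB60 rose (10.9 ± 0.961 to 17.5 ± 0.0545 CPM, log2 change 0.68, SE 0.118, edgeR adjusted p = 0.00177). In cell division 1 of 31 rose, 30 did not pass (median log2 change 0.20, none adjusted over the list alone, camera adjusted p = 0.0385, adjusted p = 0.527 with an estimated correlation). CIPK20 rose (1.94 ± 1.16 to 48.7 ± 0.215 CPM, log2 change 4.63, SE 0.254, edgeR adjusted p = 2.94e-06). DOG1 rose (0.123 ± 0.174 to 3.52 ± 0.721 CPM, log2 change 4.71, SE 0.587, edgeR adjusted p = 0.00021).

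DH9 against 2n gave fewer calls than DH6. Most salicylic acid and touch genes fell, and most photosynthesis genes, the glucosinolate regulator MYB28 and the morning clock genes CCA1 and PRR9 rose. SNL1, a scaffold of histone deacetylase complexes, was almost lost. In this comparison 1663 genes rose and 1645 fell (3308 in all). Every left-out library lowered the number, to 1896 without 2n 1, 2018 without 2n 2, 1582 without DH9 1 and 1003 without DH9 2. Of salicylic acid genes 1 of 27 rose and 21 fell, 5 did not pass (median log2 change -1.60, 1 up and 23 down adjusted over the list alone, camera adjusted p = 8.87e-13, adjusted p = 0.0845 with an estimated correlation). PR1 fell (108 ± 42.3 to 0.367 ± 0.101 CPM, log2 change -8.18, SE 1.1, edgeR adjusted p = 0.00123). FMO1 fell at least 62.2-fold (189 against 0 counts, edgeR adjusted p = 0.00206). Of touch genes 19 of 22 fell, 3 did not pass (median log2 change -2.23, 20 down adjusted over the list alone, camera adjusted p = 1e-13, adjusted p = 0.368 with an estimated correlation). WRKY46 fell (59.5 ± 11.1 to 4.36 ± 2.05 CPM, log2 change -3.78, SE 0.244, edgeR adjusted p = 1.71e-05). In photosynthesis 23 of 33 rose, 10 did not pass (median log2 change 0.48, 29 up adjusted over the list alone, camera adjusted p = 5.35e-13, adjusted p = 0.368 with an estimated correlation). LHCB2.3 rose (289.6 ± 39.7 to 1230 ± 53.8 CPM, log2 change 2.09, SE 0.106, edgeR adjusted p = 4.2e-06). In glucosinolate synthesis 13 of 25 rose, 12 did not pass (18 up adjusted over the list alone, camera adjusted p = 1.66e-06, adjusted p = 0.585 with an estimated correlation). MYB28 rose (27.1 ± 4.12 to 61.8 ± 0.405 CPM, log2 change 1.19, SE 0.129, edgeR adjusted p = 0.000256). SNL1 fell (38.1 ± 8.24 to 0.661 ± 0.306 CPM, log2 change -5.86, SE 0.317, edgeR adjusted p = 6.18e-06).

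In DH9 the clock list passed: 8 of 19 rose and 3 fell, 8 did not pass (median log2 change 0.56, 8 up and 4 down adjusted over the list alone, camera adjusted p = 0.00279, adjusted p = 0.113 with an estimated correlation). LNK2 (AT3G54500) rose (18.6 ± 0.178 to 143 ± 5.17 CPM, log2 change 2.94, SE 0.21, edgeR adjusted p = 2.27e-05) and PRR9 rose (0.818 ± 0.0974 to 6.33 ± 1.66 CPM, log2 change 2.94, SE 0.241, edgeR adjusted p = 5.24e-05). CCA1 rose (1.03 ± 0.0127 to 22.8 ± 0.623 CPM, log2 change 4.46, SE 0.474, edgeR adjusted p = 0.000234). Of NLR receptors 6 of 25 fell, 19 did not pass (median log2 change -0.23, 7 down adjusted over the list alone, camera adjusted p = 0.0125, adjusted p = 0.784 with an estimated correlation). RPP13 fell (87.2 ± 0.717 to 60.6 ± 0.503 CPM, log2 change -0.52, SE 0.0865, edgeR adjusted p = 0.00265). In heat shock 6 of 16 fell, 10 did not pass (median log2 change -1.17, 1 up and 9 down adjusted over the list alone, camera adjusted p = 0.00941, adjusted p = 0.368 with an estimated correlation). Of guard cell and trichome markers 3 of 7 rose, 4 did not pass (median log2 change 0.42, 3 up adjusted over the list alone, camera adjusted p = 0.0469, adjusted p = 0.368 with an estimated correlation), a list call lost in a paired fit. MYB60 rose (10.9 ± 0.961 to 17.2 ± 0.545 CPM, log2 change 0.66, SE 0.119, edgeR adjusted p = 0.00425). The cell wall gene XTH31 rose (2.98 ± 0.806 to 47 ± 11.6 CPM, log2 change 3.97, SE 0.252, edgeR adjusted p = 1.64e-05).

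DH14 against 2n shared the loss of SNL1 and PR1, and the morning clock genes CCA1 and PRR9 rose. The floral repressor MAF5, a relative of FLC, rose as well. The flavonoid gene TT4 and the trichome marker TRY rose in leaves of this line. Here 2437 genes rose and 2604 fell (5041 in all). Fewer passed without 2n 1 (3071), DH14 1 (3122) and DH14 2 (2267). In photosynthesis 26 of 33 rose, 7 did not pass (median log2 change 0.68, 27 up adjusted over the list alone, camera adjusted p = 5.41e-15, adjusted p = 0.472 with an estimated correlation). LHCB2.3 rose (289.6 ± 39.7 to 2263 ± 94 CPM, log2 change 2.97, SE 0.11, edgeR adjusted p = 1.02e-07) and GUN4, a factor of chlorophyll synthesis, rose (97 ± 12.6 to 339 ± 13.1 CPM, log2 change 1.81, SE 0.107, edgeR adjusted p = 1.85e-06). In salicylic acid defence 20 of 27 fell, 7 did not pass (median log2 change -1.37, 22 down adjusted over the list alone, camera adjusted p = 7.78e-09, adjusted p = 0.199 with an estimated correlation). PR1 fell (108 ± 42.3 to 1.31 ± 0.223 CPM, log2 change -6.35, SE 0.929, edgeR adjusted p = 0.000984). ALD1 fell (7.51 ± 0.251 to 0.388 ± 0.0459 CPM, log2 change -4.25, SE 0.561, edgeR adjusted p = 0.00055). Of touch genes 13 of 22 fell, 9 did not pass (median log2 change -1.26, 14 down adjusted over the list alone, camera adjusted p = 2.04e-06, adjusted p = 0.605 with an estimated correlation). In glucosinolate synthesis 16 of 25 rose, 9 did not pass (median log2 change 1.16, 21 up adjusted over the list alone, camera adjusted p = 1.24e-06, adjusted p = 0.605 with an estimated correlation). MYB29 rose (5.58 ± 1.23 to 17.1 ± 3.85 CPM, log2 change 1.61, SE 0.184, edgeR adjusted p = 0.000152). In anthocyanin synthesis 2 of 16 rose, 14 did not pass (median log2 change 0.83, 2 up adjusted over the list alone, camera adjusted p = 0.0126, adjusted p = 0.605 with an estimated correlation), with TT4 (chalcone synthase) up (34.1 ± 6.17 to 117 ± 13.7 CPM, log2 change 1.77, SE 0.256, edgeR adjusted p = 0.000654). Of guard cell and trichome markers 4 of 7 rose, 3 did not pass (median log2 change 0.60, 4 up adjusted over the list alone, camera adjusted p = 0.0197, adjusted p = 0.472 with an estimated correlation). TRY rose (0.639 ± 0.0716 to 4.03 ± 0.121 CPM, log2 change 2.64, SE 0.413, edgeR adjusted p = 0.00106).

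Single genes in DH14 moved far from 2n. SNL1 fell (38.1 ± 8.24 to 0.676 ± 0.454 CPM, log2 change -5.81, SE 0.315, edgeR adjusted p = 1.27e-06). CCA1 rose (1.03 ± 0.0127 to 94.1 ± 8.33 CPM, log2 change 6.51, SE 0.473, edgeR adjusted p = 8.07e-06) and PRR9 rose (0.818 ± 0.0974 to 27.1 ± 0.399 CPM, log2 change 5.03, SE 0.217, edgeR adjusted p = 2.67e-07). MAF5 rose (0.555 ± 0.577 to 26.8 ± 1.27 CPM, log2 change 5.61, SE 0.725, edgeR adjusted p = 0.000329). HSFA2 fell (log2 change -7.38, SE 0.991, edgeR adjusted p = 0.000419) and DREB2A fell (log2 change -4.90, SE 0.444, edgeR adjusted p = 3.31e-05). The clock list split evenly, 9 up and 9 down of 19 (camera adjusted p = 0.435). NLR receptors (1 up, 7 down, camera adjusted p = 0.119) and heat shock (5 down, camera adjusted p = 0.071) did not pass.

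Against 2n, salicylic acid genes of sDH fell again. The transporter gene UMAMIT33 and asparagine synthetase gene ASN1, which is switched on by darkness, rose. The light-harvesting gene LHCB2.3 rose with them. Here 2951 genes rose and 2877 fell (5828 in all), with a minimum 2-fold change 674 and 1323, and 3660 changed without sDH II. Salicylic acid genes again went down: 25 of 27 fell, 2 did not pass (median log2 change -3.49, 26 down adjusted over the list alone, camera adjusted p = 1.9e-19, adjusted p = 0.0263 with an estimated correlation). PR1 fell at least 1400-fold (4240 against 0 counts, edgeR adjusted p = 0.000283). WRKY54 fell (71 ± 0.396 to 12.5 ± 0.783 CPM, log2 change -2.51, SE 0.153, edgeR adjusted p = 1.58e-06). Of touch genes 21 of 22 fell, 1 did not pass (median log2 change -2.33, 22 down adjusted over the list alone, camera adjusted p = 9.38e-12, adjusted p = 0.627 with an estimated correlation). Of NLR receptors 17 of 25 fell, 8 did not pass (median log2 change -0.83, 19 down adjusted over the list alone, camera adjusted p = 2.53e-09, adjusted p = 0.627 with an estimated correlation). In photosynthesis 22 of 33 rose and 1 fell, 10 did not pass (median log2 change 0.56, 23 up and 1 down adjusted over the list alone, camera adjusted p = 2.99e-08, adjusted p = 0.627 with an estimated correlation). LHCB2.3 rose (289.6 ± 39.7 to 1787 ± 113 CPM, log2 change 2.63, SE 0.108, edgeR adjusted p = 2.17e-07). ASN1 rose (4.13 ± 1.73 to 816 ± 8.62 CPM, log2 change 7.63, SE 0.387, edgeR adjusted p = 6.09e-07) and SEN1 rose (3.1 ± 1.6 to 636 ± 159 CPM, log2 change 7.69, SE 0.407, edgeR adjusted p = 6.88e-07). UMAMIT33 rose at least 108-fold (0 against 321 counts, edgeR adjusted p = 7.18e-06).

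Of jasmonate genes 6 of 25 fell, 19 did not pass (median log2 change -1.86, 5 down adjusted over the list alone, camera adjusted p = 0.00465, adjusted p = 0.89 with an estimated correlation). TAT3 fell (76 ± 10.9 to 0.315 ± 0.28 CPM, log2 change -7.79, SE 1.28, edgeR adjusted p = 0.00101). In heat shock 7 of 16 fell, 9 did not pass (median log2 change -1.46, 1 up and 8 down adjusted over the list alone, camera adjusted p = 0.027, adjusted p = 0.627 with an estimated correlation), with HSP90.1 down (10.3 ± 0.453 to 1.14 ± 0.369 CPM, log2 change -3.14, SE 0.421, edgeR adjusted p = 0.000266). In anthocyanin synthesis 3 of 16 rose, 13 did not pass (median log2 change 0.81, 2 up adjusted over the list alone, camera adjusted p = 0.0366, adjusted p = 0.627 with an estimated correlation), with EGL3 up (0.481 ± 0.226 to 2.42 ± 0.275 CPM, log2 change 2.31, SE 0.397, edgeR adjusted p = 0.00136). Of iron genes 1 of 13 rose and 5 fell, 7 did not pass (median log2 change -1.17, 2 up and 5 down adjusted over the list alone, camera adjusted p = 0.0303, adjusted p = 0.627 with an estimated correlation). BHLH100 fell (log2 change -3.31, SE 0.85, edgeR adjusted p = 0.0128) and FER3 fell (log2 change -0.39, SE 0.0948, edgeR adjusted p = 0.0102). Without 1 library BHLH100 gave edgeR adjusted p = 0.0529 (2n 2) or 0.111 (sDH II), and FER3 0.0811 (2n 1) or 0.0636 (sDH III). Glucosinolate genes (2 up, 3 down, camera adjusted p = 0.237) and the senescence list (5 up, 5 down, camera adjusted p = 0.618) did not pass in sDH.

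**Figure D3:**
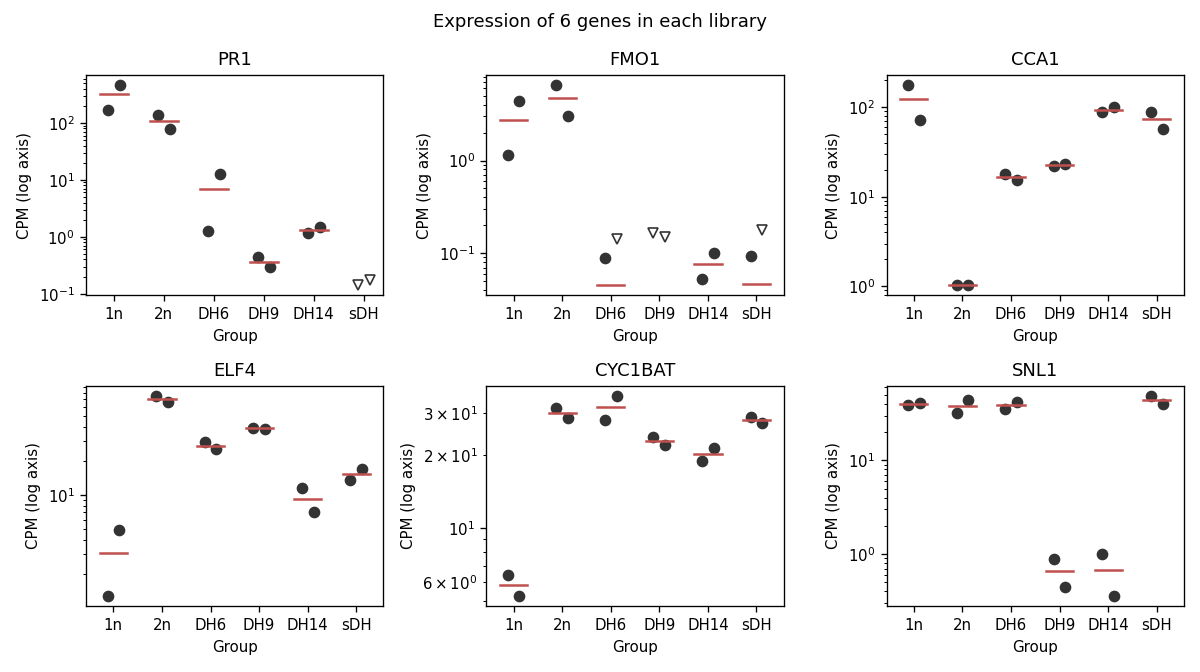
Levels of PR1, FMO1, CCA1, ELF4, CYC1BAT and SNL1 in each library on a log axis. Open triangles stand for libraries without a count, drawn at their floor of 3 counts, and red lines are group means.

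DH6, DH9 and DH14 differed from each other in 4857 genes by edgeR's F-test. DH6 carried most of this. Between DH9 and DH14 299 genes were higher in DH9 and 297 lower, against 1364 and 1791 between DH6 and DH9 and 2430 and 2708 between DH6 and DH14. The F-test gave 2618 genes without DH6 II, 2162 without DH6 III, 3082 without DH14 1 and 2840 without DH14 2. Of NLR receptors in DH6 against DH9 14 of 25 fell, 11 did not pass (16 down adjusted over the list alone, camera adjusted p = 2.13e-08, adjusted p = 0.347 with an estimated correlation). Against DH14 16 of 25 fell, 9 did not pass (20 down adjusted over the list alone, camera adjusted p = 1.09e-07, adjusted p = 0.45 with an estimated correlation). Of touch genes in DH6 against DH9 12 of 22 fell, 10 did not pass (16 down adjusted over the list alone, camera adjusted p = 3.35e-07, adjusted p = 0.347 with an estimated correlation). Against DH14 19 of 22 fell, 3 did not pass (20 down adjusted over the list alone, camera adjusted p = 1.15e-10, adjusted p = 0.45 with an estimated correlation). In salicylic acid defence against DH9 1 of 27 rose and 11 fell, 15 did not pass (1 up and 13 down adjusted over the list alone, camera adjusted p = 2.79e-05, adjusted p = 0.347 with an estimated correlation). Against DH14 16 of 27 fell, 11 did not pass (17 down adjusted over the list alone, camera adjusted p = 4.76e-07, adjusted p = 0.351 with an estimated correlation). In cell division against DH9 6 of 31 rose, 25 did not pass (6 up adjusted over the list alone, camera adjusted p = 2.79e-05, adjusted p = 0.347 with an estimated correlation). Against DH14 7 of 31 rose, 24 did not pass (5 up adjusted over the list alone, camera adjusted p = 0.000288, adjusted p = 0.475 with an estimated correlation). Senescence against DH9: 9 of 15 fell, 6 did not pass (10 down adjusted over the list alone, camera adjusted p = 5.9e-05, adjusted p = 0.347 with an estimated correlation). Against DH14 7 of 15 fell, 8 did not pass (7 down adjusted over the list alone, camera adjusted p = 0.0011, adjusted p = 0.45 with an estimated correlation). In iron homeostasis against DH9 7 of 13 rose, 6 did not pass (7 up adjusted over the list alone, camera adjusted p = 0.0168, adjusted p = 0.347 with an estimated correlation). Against DH14 6 of 13 rose, 7 did not pass (7 up adjusted over the list alone, camera adjusted p = 0.00766, adjusted p = 0.45 with an estimated correlation).

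Smaller lists passed between lines as well. DNA damage in DH6 against DH9: 1 of 16 rose, 15 did not pass (1 up adjusted over the list alone, camera adjusted p = 0.0168, adjusted p = 0.347 with an estimated correlation), and against DH14 2 of 16 rose, 14 did not pass (1 up adjusted over the list alone, camera adjusted p = 0.0125, adjusted p = 0.416 with an estimated correlation). Centromere genes against DH9: 1 of 8 rose, 7 did not pass (1 up adjusted over the list alone, camera adjusted p = 0.0432, adjusted p = 0.347 with an estimated correlation). Anthocyanin genes passed as a list against DH9 without a single member called (camera adjusted p = 0.0168, adjusted p = 0.347 with an estimated correlation). Photosynthesis in DH6 against DH14: 17 of 33 fell, 16 did not pass (19 down adjusted over the list alone, camera adjusted p = 0.000169, adjusted p = 0.653 with an estimated correlation). Jasmonate genes there: 4 of 25 fell, 21 did not pass (3 down adjusted over the list alone, camera adjusted p = 0.0272, adjusted p = 0.8 with an estimated correlation). In DH9 against DH14 photosynthesis genes were lower: 9 of 33 fell, 24 did not pass (14 down adjusted over the list alone, camera adjusted p = 2.6e-07, adjusted p = 0.791 with an estimated correlation). Of touch genes 3 of 22 fell, 19 did not pass (5 down adjusted over the list alone, camera adjusted p = 3.6e-06, adjusted p = 0.791 with an estimated correlation). Of cold and abscisic acid genes 6 of 26 rose and 1 fell, 19 did not pass (12 up and 2 down adjusted over the list alone, camera adjusted p = 0.000444, adjusted p = 0.813 with an estimated correlation). Of anthocyanin genes 1 of 16 fell, 15 did not pass (2 down adjusted over the list alone, camera adjusted p = 0.00219, adjusted p = 0.791 with an estimated correlation). Jasmonate genes passed there as a list without a single member called (camera adjusted p = 0.0114, adjusted p = 0.996 with an estimated correlation).

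Several genes moved the same way in all 3 lines. Against 1n, CAX3, a vacuolar calcium exchanger, fell in DH6 (log2 change -6.17, SE 0.565, edgeR adjusted p = 1.51e-05), DH9 (log2 change -5.72, SE 0.549, edgeR adjusted p = 4.69e-05) and DH14 (log2 change -5.54, SE 0.54, edgeR adjusted p = 0.00011). The defence gene AIG1 fell in DH6 (log2 change -5.57, SE 0.8, edgeR adjusted p = 0.000239), DH9 (log2 change -7.49, SE 0.977, edgeR adjusted p = 0.000292) and DH14 (log2 change -6.82, SE 0.913, edgeR adjusted p = 0.000637). Against 2n, ALD1, the first enzyme toward pipecolic acid, fell in DH6 (log2 change -5.49, SE 0.631, edgeR adjusted p = 0.000194), DH9 (log2 change -5.78, SE 0.669, edgeR adjusted p = 0.000577) and DH14 (log2 change -4.25, SE 0.561, edgeR adjusted p = 0.00055). FMO1 fell in DH6 with a count ratio of 105 (95% interval 28.7 to 874, edgeR adjusted p = 0.00125) and in DH14 with a count ratio of 62.6 (95% interval 21.1 to 306, edgeR adjusted p = 0.00192). DOG1 rose in DH6 (log2 change 4.71, SE 0.587, edgeR adjusted p = 0.00021), DH9 (edgeR adjusted p = 0.0012) and DH14 (log2 change 4.86, SE 0.584, edgeR adjusted p = 0.000205).

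Of genes called in all 3 lines against 1n, 1582 rose and 1472 fell (81.5 and 82.7 if independent, which the shared controls rule out). Against 2n 777 rose and 796 fell (25.2 and 29.4). Adding sDH left 1503 genes higher and 1345 lower against 1n, and 604 and 721 against 2n. In all 5 diploid groups against 1n 1349 genes rose and 1001 fell. Log2 changes of DH6 and DH9 against 1n had a covariance of 0.652 (r = 0.744). For DH6 and DH14 it was 0.522 (r = 0.689), and for DH9 and DH14 0.529 (r = 0.812). Against 2n the covariances were 0.45, 0.451 and 0.432 (r = 0.677, 0.635 and 0.771). Simulated covariances (at most 0.00206) set no chance level, since chance deviation of the controls was left out. With the second line of a pair set against the other control r was 0.144, -0.0322 and -0.0659 (first line against 1n) and 0.0994, 0.115 and 0.159 (first line against 2n), so that r depends on the shared control. Across controls the overlaps went both ways. Genes higher in DH6 against 1n and also in DH9 or DH14 against 2n numbered 172 and 239 (375 and 550 if independent), in DH9 against 1n and DH6 or DH14 against 2n 426 and 232 (354 and 377), and in DH14 against 1n and DH6 or DH9 against 2n 366 and 178 (278 and 202). In the same order, lower ones numbered 668, 613, 719, 448, 559 and 408 (404, 639, 376, 386, 299 and 194). With 2 control libraries the controls cannot be split, and a control pair that differs from its own population would add to all of these overlaps.

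Calls against both controls differ in the controls and share the libraries of the group. DH6 had 890 genes higher and 1713 lower than both 1n and 2n (517 and 622 if independent, which the shared libraries rule out), DH9 247 and 508 (257 and 244), DH14 363 and 567 (296 and 308), and sDH 1478 and 1837 (712 and 702).

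Genes of the DNA methylation machinery and CENH3 were read in each comparison. Against 1n, MET1, which keeps CG methylation, rose in 2n (log2 change 0.73, SE 0.117, edgeR adjusted p = 0.000593), DH6 (log2 change 0.72, SE 0.117, edgeR adjusted p = 0.000501), DH9 (log2 change 0.72, SE 0.117, edgeR adjusted p = 0.00107), DH14 (log2 change 0.57, SE 0.117, edgeR adjusted p = 0.00562) and sDH (log2 change 0.46, SE 0.117, edgeR adjusted p = 0.00708). CMT3, the CHG methyltransferase, rose in 2n (log2 change 0.95, SE 0.125, edgeR adjusted p = 0.000153), DH6 (log2 change 0.94, SE 0.125, edgeR adjusted p = 0.000141), DH9 (log2 change 0.75, SE 0.125, edgeR adjusted p = 0.00127), DH14 (log2 change 0.66, SE 0.125, edgeR adjusted p = 0.00412) and sDH (log2 change 0.84, SE 0.125, edgeR adjusted p = 0.000271). The remodeler DDM1 (CHR1) rose in 2n (log2 change 0.65, SE 0.127, edgeR adjusted p = 0.002), DH6 (log2 change 1.00, SE 0.125, edgeR adjusted p = 1e-04), DH9 (log2 change 0.69, SE 0.127, edgeR adjusted p = 0.00223), DH14 (log2 change 0.87, SE 0.126, edgeR adjusted p = 0.00095) and sDH (log2 change 1.00, SE 0.126, edgeR adjusted p = 9.11e-05). The demethylase ROS1 (DML1) rose in 2n (log2 change 0.58, SE 0.132, edgeR adjusted p = 0.00476), DH9 (log2 change 0.91, SE 0.132, edgeR adjusted p = 0.000573), DH14 (log2 change 0.97, SE 0.132, edgeR adjusted p = 0.000708) and sDH (log2 change 0.48, SE 0.132, edgeR adjusted p = 0.0115) and did not pass in DH6 (log2 change 0.10, SE 0.132, edgeR adjusted p = 0.555). CMT2 rose in DH14 (log2 change 0.67, SE 0.178, edgeR adjusted p = 0.0203) and sDH (log2 change 0.69, SE 0.178, edgeR adjusted p = 0.00828), and not in 2n (log2 change -0.26, SE 0.18, edgeR adjusted p = 0.274), DH6 (log2 change 0.23, SE 0.178, edgeR adjusted p = 0.318) or DH9 (log2 change 0.26, SE 0.178, edgeR adjusted p = 0.293). DRM2 rose in sDH (log2 change 0.46, SE 0.136, edgeR adjusted p = 0.0156, though DESeq2 gave 0.0684) and in no other group against 1n. CENH3 (HTR12) passed edgeR in none of these comparisons, with its smallest adjusted p in DH6 (log2 change 0.59, SE 0.307, edgeR adjusted p = 0.138). Some of these calls turned on 1 library. In DH14, CMT2 gave edgeR adjusted p = 0.0801 without 1n 1, 0.0667 without DH14 1 and 0.103 without DH14 2. In sDH, edgeR adjusted p rose to 0.0509 for CMT2, 0.0599 for MET1, 0.143 for ROS1 and 0.083 for DRM2 without sDH II, and to 0.0504 for ROS1 and 0.119 for DRM2 without 1n 2. CMT2 passed edgeR in 2n without 1n 1 (adjusted p = 0.0141) and in DH6 and DH9 without 1n 2 (0.0118 and 0.0136), and CENH3 in DH6 without DH6 II (0.00999).

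Against 2n, CMT2 rose in DH14 (log2 change 0.93, SE 0.178, edgeR adjusted p = 0.00356) and sDH (log2 change 0.95, SE 0.178, edgeR adjusted p = 0.00233), ROS1 (DML1) fell in DH6 (log2 change -0.48, SE 0.131, edgeR adjusted p = 0.0202), and DRM2 (log2 change 0.47, SE 0.134, edgeR adjusted p = 0.0218) and DDM1 (CHR1, log2 change 0.35, SE 0.12, edgeR adjusted p = 0.0492) rose in sDH. DESeq2 also passed CMT2 in DH6 and DH9 (adjusted p = 0.0431 and 0.0375) and ROS1 in DH14 (0.0434), and did not pass DRM2 and DDM1 in sDH (0.0883 and 0.201). MET1, CMT3 and CENH3 passed edgeR in no comparison against 2n. ROS1 in DH6 gave edgeR adjusted p = 0.129 without 2n 2, 0.102 without DH6 II and 0.0788 without DH6 III. In sDH, DRM2 gave edgeR adjusted p = 0.0532, 0.115, 0.114 and 0.0594 without 2n 1, 2n 2, sDH II and sDH III, and DDM1 0.283, 0.156 and 0.137 without 2n 1, sDH II and sDH III. DDM1 in DH6 (edgeR adjusted p = 0.0547) passed without 2n 2 (0.0378). Among the 3 lines only ROS1 of these genes differed (58.3, 102 and 106 CPM in DH6, DH9 and DH14, edgeR adjusted p = 0.00176). The others gave edgeR adjusted p = 0.515 for MET1, 0.13 for CMT2, 0.204 for CMT3, 0.332 for DRM2, 0.165 for DDM1 and 0.373 for CENH3.

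Transposable elements, which DNA methylation keeps silent, were more often higher than lower in all diploid groups against 1n. In 2n 225 TEs rose and 139 fell, in DH6 275 and 181, in DH9 190 and 95, in DH14 136 and 76 and in sDH 339 and 181. The share that rose depends on scaling: with TMM on the TE counts it went from 61.8 to 53.1% in 2n, 60.3 to 46% in DH6, 66.7 to 48.5% in DH9, 64.2 to 50.7% in DH14 and 65.2 to 47.5% in sDH. Median log2 changes over all tested TEs were 0.112 in 2n, 0.174 in DH6, 0.148 in DH9, 0.129 in DH14 and 0.239 in sDH. Left-out libraries lowered the number of changed TEs from 364 to 230 in 2n (without 2n 2), 456 to 293 in DH6 (DH6 III), 285 to 146 and 121 in DH9 (DH9 1, DH9 2) and 212 to 84 in DH14 (DH14 2). AT3TE43945 rose in 2n at least 86-fold (0 against 311 counts, edgeR adjusted p = 0.00178) and also in DH6 (37.3 and 5.22 CPM, edgeR adjusted p = 0.000164). AT5TE48740 fell in 2n at least 36.6-fold (91 against 0 counts, edgeR adjusted p = 2.25e-05) and AT5TE40480 rose in DH6 at least 60.2-fold (0 against 242 counts, edgeR adjusted p = 0.000131). AT5TE29665 fell in DH6 at least 52.3-fold (117 against 0 counts, edgeR adjusted p = 0.00015). For AT5TE40480, at 1.03 CPM in sDH II, DESeq2 gave adjusted p = 0.0953. Whether the counts of DH6 at silent TEs add to its TE rises was not tested. AT5TE37875 rose in DH9 (0.403 ± 0.0556 to 5.08 ± 0.965 CPM, log2 change 3.63, SE 0.384, edgeR adjusted p = 4.96e-06) and DH14 (to 8.02 ± 1.58 CPM, log2 change 4.29, SE 0.375, edgeR adjusted p = 9.25e-07). In all 3 lines together 81 TEs rose and 44 fell against 1n, and 19 and 28 against 2n.

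Against 2n, 94 TEs rose and 113 fell in DH6, in DH9 89 and 77, in DH14 131 and 122, and in sDH 183 and 116. With TMM on the TE counts the share that rose went from 45.4 to 33.5% in DH6, 53.6 to 47.6% in DH9, 51.8 to 49.2% in DH14 and 61.2 to 43.3% in sDH. With a minimum 2-fold change 44 rose and 100 fell in DH6, and 84 and 98 in sDH. Medians over all tested TEs were 0.121 in DH6, 0.037 in DH9, 0.002 in DH14 and 0.198 in sDH. Leaving out 2n 1, 2n 2 and the line's libraries in turn took the 207 calls in DH6 to 133, 119, 108 and 112. The 166 in DH9 went to 91, 94, 84 and 66 and the 253 in DH14 to 112, 157, 165 and 104. The 299 in sDH went to 197 without 2n 1 and 185 without sDH II. AT5TE40480 rose in DH6 at least 72.5-fold (0 against 242 counts, edgeR adjusted p = 0.000175, though DESeq2 gave 0.146). AT3TE45385 rose in DH9 (0.234 ± 0.123 to 5.04 ± 0.0664 CPM, log2 change 4.41, SE 0.506, edgeR adjusted p = 2.04e-05) and AT2TE35695 in sDH (0.434 ± 0.0836 to 13.1 ± 3.3 CPM, log2 change 4.89, SE 0.641, edgeR adjusted p = 2.28e-05). AT4TE64410, lowest in 2n, rose in DH14 (1.53 ± 0.274 to 31.2 ± 2.67 CPM, log2 change 4.34, SE 0.195, edgeR adjusted p = 3.03e-11) beside 24.2 and 24.1 CPM in 1n. AT3TE63500 rose in sDH at least 84.3-fold (0 against 250 counts, edgeR adjusted p = 6.91e-07). Among DH6, DH9 and DH14 244 TEs differed (137 without DH6 II, 127 without DH6 III), 178 between DH6 and DH9, 252 between DH6 and DH14 and 18 between DH9 and DH14. Of 8 listed copies with known mobility 7 were tested, and the calls among them were falls in DH6 (1 against each control), DH14 (1 against 2n) and sDH (2 against each control).

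Other lists passed camera in none of the comparisons against 1n or 2n. Root markers had 3 of 11 members tested (smallest camera adjusted p = 0.246), flower and pollen markers 5 of 14 (0.0894), endocycle genes 9 (0.223) and phosphate starvation genes 7 of 12 (0.237). For cold and abscisic acid the smallest value was 0.119 with 26 of 28 tested, for flowering time 0.15 with 17 of 22, and for loci silenced by DNA methylation 0.148 with 5 of 18. Seed markers (11 listed) and shoot meristem markers (5 listed) had no member with enough counts to be tested.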

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

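The differences among DH6, DH9 and DH14 given here were looked for by a fixed rule, and the tests of explanations in this part were chosen only after the results were seen. Among the 3 lines 4857 genes and 244 TEs differed by edgeR's F-test. Of 151 named genes of the DH comparisons 84 were among them, and of 19 named TEs 12. Named features that passed the F-test are given as these counts only, except for ROS1 and those called in opposite directions in 2 lines.

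Opposite calls against 1n were found in 6 genes. RPS2 was lower in DH6 (log2 change -0.50) and, unless adjusted over its list alone, higher in DH9 (0.43, edgeR adjusted p = 0.00155 between them). CYP81F2, an indolic glucosinolate enzyme, was lower in DH6 (-1.80) and higher in DH9 and DH14 (1.16 and 1.87), with edgeR adjusted p = 0.000713 and 0.000114. TCH3 was lower in DH6 (-2.58) and higher in DH14 (0.77, edgeR adjusted p = 6.98e-05). WRKY53 was lower in DH6 (-2.43, edgeR adjusted p = 0.000114 against DH14) and DH9 (-1.01, edgeR adjusted p = 0.00391) and higher in DH14 (0.97). ASN1 was lower in DH6 (-2.76) and higher in DH14 (1.01, edgeR adjusted p = 0.000114), as was PHI-1 (-4.21 and 1.32, edgeR adjusted p = 0.00014). Against 2n, NAP was lower in DH6 (-3.23) and higher in DH14 (2.08, edgeR adjusted p = 0.00017). The TE AT3TE45385 had no count in DH6 and 194 counts in DH9, beside 24 in 1n and 9 in 2n, and was lower in DH6 and higher in DH9 than either control (edgeR adjusted p = 8.13e-07 between the lines). ROS1 (DML1) was lower in DH6 than in DH9 and DH14 (edgeR adjusted p = 0.00176 over the 3 lines).

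Clock genes differed between most groups. If leaves were taken at different hours, 8 morning and 7 evening genes should move in opposite directions, and their medians had opposite signs in all 15 pairs of groups. Ploidy alone would leave DH14 and 2n alike, yet 18 of 19 clock genes differed between them. A difference in harvest hour or clock phase fits these values, and the 2 cannot be told apart without the hour of harvest.

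As a list, salicylic acid genes were lower in DH6, DH9, DH14 and sDH than in both controls at camera's preset correlation, but with the estimated correlation only in DH6 and sDH against 2n. Ploidy alone would lower them in 2n as well, where the list's median log2 change against 1n was 0.14. All 4 libraries of DH14 and sDH lay nearer to a 1n library in clock genes (0.382 to 0.495) than the 1n libraries to each other (0.681). All 4 still had lower list means than both, by 1.1 to 3.15 against a gap of 0.354 in 1n. Clock genes still differed from 1n in DH14 (6 up, 1 down) and sDH (7 up, 3 down), so time of day stays open. In DH6 and DH9 0 libraries were near enough to tell. No label names a preparation batch. Column names part 1n and 2n (4 libraries) from the rest (8), so batch is open wherever these sets are compared.

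Counts at silent features in DH6 were weighed against depth, TE release and contamination. Thinned to equal totals, the lower DH6 library still had 3756 TEs with a count, beside at most 2760 in the other groups, which speaks against deeper sequencing. Release of TEs alone would spare genes, yet among genes silent in the 4 groups other than DH6 and the group set beside it, at least 9.59% had a count in a DH6 library and at most 5.49% in a library of the other group, after thinning. Genomic DNA in the RNA would add counts on all chromosomes and in organelle genes. The shares differed between chromosomes by ratios of 1.24 and 1.3 at most, and organelle genes took 0.0537% at most, inside the range of the other groups, so that this explanation stays open.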

How the results depend on the processing

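Among the 484 named results, none that passed in the main fit reversed its direction under any alternative. None that did not pass there came to pass in the opposite direction. With TMM on the TE counts the calls against 1n turned from mostly higher to mostly lower in DH6, DH9 and sDH (46, 48.5 and 47.5% higher). Of 4818 values for the named results 4506 kept their side of the threshold, 290 were weaker and 22 stronger, and 138 named results moved at least once. A minimum log2 change of 1 gave 74 weaker values, leaving out a library, tried for several libraries per result, 154 weaker and 6 stronger, and the DESeq2 test 28 weaker and 3 stronger. Fitting only the groups compared gave 18 weaker and 4 stronger. With only the groups compared the numbers of genes fell to 4399 in 2n against 1n, 3028 in DH9 against 1n and 1628 in DH14 against 1n. It gave more in DH9 against 2n (3738), DH14 against 2n (5251) and among the lines (6953). A minimum 2-fold change left 2763, 3221, 1868, 1303 and 3412 genes for 2n, DH6, DH9, DH14 and sDH against 1n, 1774, 920, 1419 and 1997 for DH6, DH9, DH14 and sDH against 2n, and 1440 among the lines. It left 303, 175 and 128 TEs in DH6, DH9 and DH14 against 1n, 154 and 182 in DH14 and sDH against 2n and 162 among the lines, by its construction. The estimated correlation in camera left 1 list in DH6 and sDH against 2n and 0 elsewhere, where the preset correlation gave 5, 10, 4, 4 and 8 lists against 1n and 10, 8, 6 and 8 against 2n. Comparing DH9 with DH14 with DH6 left out of the fit gave 448 genes and 17 TEs. The repeated 1n column in the sDH table gave 11633 genes against 1n, beside 6617 with both 1n libraries in the same small fit, since a repeated column has no spread. For other moved values the cause was not tested.

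Leaving out each library in turn gave ranges of 6007 to 7295 genes for 2n, 6442 to 8702 for DH6, 3059 to 5708 for DH9, 2205 to 4447 for DH14 and 6910 to 8964 for sDH against 1n. Against 2n they were 2632 to 3931, 1003 to 2018, 2267 to 3619 and 3660 to 4554 for DH6, DH9, DH14 and sDH, and among the lines 2162 to 3656. For TEs the ranges were 230 to 328, 293 to 429, 121 to 268, 84 to 221 and 370 to 493 against 1n, 108 to 133, 66 to 94, 104 to 165 and 185 to 221 against 2n, and 127 to 184 among the lines. For these ranges the cause was not tested.

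A replicate block, which treats libraries with the same number as paired, gave 6643 genes in 2n against 1n, 4541 in DH9 against 1n, 3125 in DH14 against 1n, 2087 in DH9 against 2n and 3756 in DH14 against 2n, and 327, 251, 202, 157 and 225 TEs. The 8 numbered libraries without the block gave 2523 genes in DH9 against 2n. With the block 5, 4, 5, 7 and 6 lists passed. Flower and pollen markers then passed in DH14 against 1n (camera adjusted p = 0.0444, beside 0.0894), and guard cell markers did not in DH9 against 2n (0.0518, beside 0.0469). The jasmonate list in 2n against 1n went from up to down and passed in neither fit (0.996, beside 0.942). Differences between numbered libraries correlated by -0.14 to 0.13 between groups, and no reason for pairing is given. DH6, sDH and the 3 lines together were not fitted as pairs, since columns of DH6 and sDH carry II and III where the labels have 1 and 2, and a paired fit of DH9 against DH14 was not made. Of 31189 TEs 1372 had enough counts to be tested.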

Other observations

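The genes in this part were picked after their values were seen. SNL1 stood at 32.3 to 48.9 CPM in the libraries of 1n, 2n, DH6 and sDH and at 0.355 to 0.998 CPM in DH9 and DH14 (edgeR adjusted p = 4.98e-06 among the lines). AT3G01319, whose locus number comes right before that of SNL1, had no count in the 4 libraries of DH9 and DH14 and 1.21 to 4.51 CPM elsewhere (edgeR adjusted p = 0.000404).

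The repressor of flowering FLC stood at 0 and 0.0632 CPM in the 1n libraries and rose in all other groups against 1n, with edgeR adjusted p = 0.0788 over the 3 lines and 0.0363 between DH6 and DH14. MAF5 was lowest in 2n (0.148 and 0.963 CPM) and highest in DH14 (27.7 and 25.9 CPM, edgeR adjusted p = 0.00665 among the lines), and MAF4 differed among the lines too (edgeR adjusted p = 0.00468). TEM1, another repressor, was lower in DH6 (17.9 and 21.3 CPM) than in DH9 and DH14 (edgeR adjusted p = 0.00279 among the lines). DOG1 stood at 0.246 and 0 CPM in 2n and at 1.94 CPM or more in each other library.

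AT2G08986 had 7.06 and 12.6 CPM in DH6, 2.15 CPM in sDH II and no count in the other libraries (edgeR adjusted p = 0.00677 among the lines). AT2G07981 had 0.36 and 2.32 CPM in DH6 and 0.84 CPM in sDH II, again with none elsewhere, with edgeR adjusted p = 0.0569 among the lines and 0.0475 in DH6 against 1n. The TE AT2TE25440 went down with PR1, and neither had a count in sDH. Whether its counts are reads of PR1 was not tested.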
